A study of Homo sapiens with 6 samples.

How the data were processed

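Poly(A) RNA came from 6 cultures labelled MKN-45, 3 control and 3 labelled NNMT knockdown. It was sequenced as paired reads of 150 bases on an Illumina NovaSeq instrument, per the labels' protocols. The labels disagree on the transfected RNA: the treatment protocol names siRNA delivered with a lipid reagent, while other fields name shRNA. They also disagree on the controls, which the design text calls untouched while the genotype label and the column headers name a negative-control shRNA. For the library kit, an NEBNext kit and a stranded Illumina protocol are both named. The replicate numbers and groups were taken from the sample titles.

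The authors deposited a table of raw read counts per gene. Counts were made with featureCounts 2.0.6 on coordinate-sorted alignments to hg38 with the GENCODE 44 annotation, per the file headers. GRCh38 is also named in the submitters' processing notes. The aligner is not given in the sources used here. The count command kept only pairs with both mates aligned (-B) and dropped chimeric pairs (-C), and neither multi-mapping reads nor reads overlapping several genes were counted, per the file headers. It did not ask for read pairs to be counted as 1 fragment. Among genes with 2 to 10 counts, 73.4% to 76.7% of the counts were even, against 49.8% to 50.7% at 1000 counts or more, which fits mates counted singly. A count of 2 therefore often stands for 1 fragment, and counting intervals based on reads are too narrow. No strand option was set, so reads of a gene and of an overlapping or antisense gene cannot be told apart. Reads shared by near-identical copies that aligned to several places were left out, so counts of multigene families are uncertain.

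The table held 62700 genes, all matched to a symbol by identifier. Gene types came from GENCODE 29, which lacked 4493 of the genes, and coordinates came from the deposited table. No column of per-sample values was left unused. Library totals ranged from 40558680 to 56067484 reads. A gene with 0 reads in a library allows up to 3 reads, or 0.0535 to 0.074 CPM depending on the library. These floors treat reads as independent, so they are too low for mates counted singly. Pairs of libraries were checked for duplicates with a chi-square statistic over genes with at least 20 reads in the pair.

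Genes were filtered with filterByExpr at its defaults, which kept 20250 genes, and libraries were scaled with TMM. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3, robust dispersion, group as the sole term) with Benjamini-Hochberg adjustment and a threshold of 0.05, and a fitted fold change of 2 as a size threshold. The biological coefficient of variation was 18.3%. Standard errors were derived from the fold change and its F statistic. NNMT did not pass the filter, so its fold change came from the same fit with NNMT added to the filtered genes. CPM, the usual count of reads scaled to a common library total, was computed here from the library totals for single libraries and for group means.

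Of 42 gene lists, 41 had at least 5 tested genes and were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over lists. Members were counted by their adjusted p over all genes and adjusted over the list alone. Named genes are NNMT, up to 10 genes per direction past the threshold with the largest fold change, a mean of at least 5 CPM and no overlap between groups, and up to 4 tested members with the lowest p of each list described. The rule also took the most abundant genes past the threshold. As no gene passed, the 5 genes with the lowest p per direction were named instead. Samples, tests, lists, this rule and all other settings but those named below were fixed before the data were examined.

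The alternatives were other scalings, other filters, DESeq2 1.42.0, limma-voom, the replicate number as a block, non-robust dispersion, thinning to the smallest library, leaving out each library in turn, stricter thresholds, and other tests of lists. Halved counts, an offset for gene length, a restriction to protein-coding genes, and camera with an estimated correlation when a library was left out or the block was used were added after the data were seen. The test was checked on data simulated from the real means and library sizes, with 200 genes changed in each of 5 simulations of 20250 genes. At a mean of at least 5 CPM it recovered 50.5% of genes changed 1.5-fold, 89.4% of those changed 2-fold and 94.9% of those changed 4-fold. Over all levels the shares were 28.7%, 53.7% and 75.8%. It made 60 false calls over these simulations and called 5 of 20250 genes in a simulation without changes. A list shifted by 0.3 on the log2 scale was called in 5 of 5 simulations, and 1 list was called in the simulation without changes. Genes were drawn independently at the fitted dispersions, so neither correlation between genes nor error in the dispersions was simulated. The shares recovered may therefore be too high for the real data. The shifted list, that of ribosomal proteins, had a median log2 fold change of only 0.107 in the real data. Figures were drawn with matplotlib 3.10.9 and exact permutation tests were enumerated over the 10 splits of the libraries. A further test of the identity of the cells is not reported here.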

Results

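RNA sequencing was carried out on cells labelled MKN-45, an established human gastric adenocarcinoma cell line. Whether the cells were of that line stays open, as described at the end. The cultures were labelled as control or as NNMT knockdown by a transfected RNA. The labels disagree on the control cells. The design text calls them untouched, while the genotype label and the column headers of the counts name a negative-control shRNA. NNMT encodes nicotinamide N-methyltransferase, the enzyme that methylates nicotinamide with S-adenosylmethionine as the methyl donor. There were 3 control libraries and 3 libraries labelled NNMT knockdown, with harvest given as 48 h after transfection, and the labels call the 3 of each condition independent biological replicates. Gene-level read counts summed to 41591436, 48215685 and 56067484 in control replicates 1, 2 and 3. They summed to 40558680, 45405621 and 43455163 in replicates 1, 2 and 3 labelled NNMT knockdown. Reads fell on 28367 to 30679 genes per library, and 3.9% to 4.82% of reads came from the mitochondrial genome. Intervals and floors given for single libraries cover counting error only, and they understate it because mates were counted singly.

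NNMT (ENSG00000166741.8) lies on the plus strand of chromosome 11, from 114257787 to 114313536 in hg38, and its merged exons span 2596 bases. The first question was whether its RNA was lowered in the libraries labelled as knockdown. NNMT was near the detection limit in all 6 libraries. Control replicates 1, 2 and 3 held 0, 8 and 12 NNMT reads, and replicates 1, 2 and 3 labelled knockdown held 2, 8 and 14. The mean level was 0.127 ± 0.112 CPM (SD, n = 3) in control libraries and 0.183 ± 0.137 CPM (SD, n = 3) in those labelled knockdown. The 0 reads of control replicate 1 allow a level of up to 0.0721 CPM if each read is independent. As mates were counted singly, the true limit is higher. For comparison, the median level over all tested genes was 9.57 CPM, and 21494 genes lay above NNMT. Reads overlapping several genes were not counted, so a low count need not mean a low RNA level.

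The fitted log2 fold change of NNMT was 0.48 (SE 0.929), with a 95% interval of the fold from 0.336 to 5.78 and an adjusted p of 0.999 in edgeR's quasi-likelihood test. An exact two-sided permutation test of log2 CPM gave p = 0.6, where the 10 splits of 6 libraries allow no p below 0.1. The fitted log2 fold change was -0.188 without replicate 3 labelled knockdown and -0.0428 without control replicate 1. With all libraries the estimate lay above control, but its interval was wide and its sign depended on single libraries. A knockdown could be neither shown nor excluded, and the wording "labelled NNMT knockdown" is kept for those libraries throughout. No decrease in NNMT was detected.

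**Figure D1:**
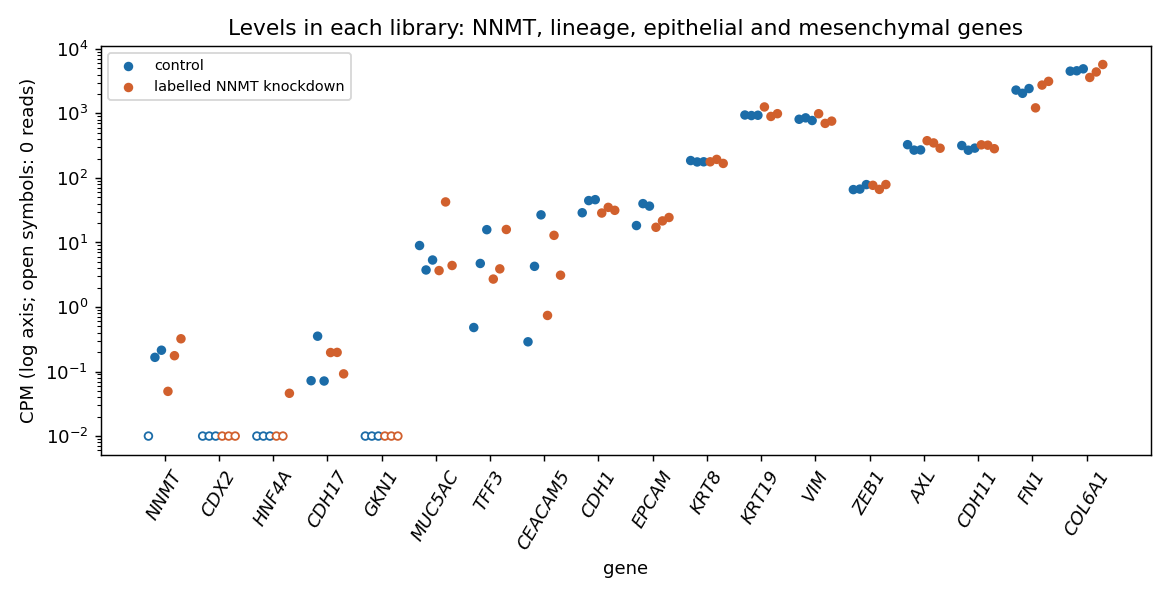
Levels of NNMT and of lineage, epithelial and mesenchymal genes in each library, in CPM on a log axis, with blue points for control and orange points for libraries labelled NNMT knockdown (replicates 1, 2 and 3 of each group from left to right). Open symbols at the bottom stand for 0 reads and do not mark a level. NNMT lay at or below 0.322 CPM in every library, while VIM lay between 701 and 990 CPM.

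The level of well-known lineage genes describes the cells that were sequenced; apart from MUC5AC, FOXA2 and SPDEF, the genes named here were chosen after their values were seen. Epithelial keratins were abundant in every library. KRT19 averaged 936 ± 8.64 CPM in control and 1050 ± 189 CPM in libraries labelled NNMT knockdown (SD, n = 3 each), and KRT8 averaged 180 ± 5.03 and 180 ± 13.1 CPM. The 46 genes of the mesenchymal transition list had a median level of 49.3 CPM, with 6 of them below 1 CPM in all libraries, against medians of 0.052 and 0.0654 CPM for the gastric and intestinal lists. The intermediate filament gene VIM averaged 814 ± 38.4 and 817 ± 153 CPM, and the collagen VI gene COL6A1 averaged 4670 ± 207 and 4570 ± 1070 CPM. Most genes of the gastric and intestinal lineages were near 0. The intestinal transcription factor gene CDX2 and the gastric gene GKN1 had 0 reads in all 6 libraries, HNF4A had 2 reads in total, and the secreted mucin gene MUC5AC lay between 3.67 and 42.5 CPM. Other members were present: 4 lay above 50 CPM in every library, among them the transcription factor genes FOXA2, at 85.1 ± 3.06 and 95.4 ± 9.07 CPM, and SPDEF, at 71 ± 1.29 and 89.8 ± 14.2 CPM. Of 65 gastric and intestinal list members, 44 lay below 1 CPM over the 6 libraries with an upper 95% counting bound also below 1 CPM.

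The Pearson correlation of log2 CPM across genes lay between 0.9802 and 0.986 within groups and between 0.9807 and 0.989 between groups, with means of 0.9828 and 0.9833. Genes are not independent replicates, so these values only describe similarity. The highest correlation, 0.989, joined control replicate 3 and replicate 3 labelled NNMT knockdown. The first principal component held 27.4% of the variance and the second 23.4%, and exact permutation tests of the group difference on them gave p = 0.8 and p = 0.9, where 0.1 is the smallest possible. The third component held 21.5% (exact permutation p = 0.2), with scores of 25.5, 29.9 and 3.03 in replicates 1, 2 and 3 labelled NNMT knockdown and of -33.1, -31.5 and 6.14 in control replicates 1, 2 and 3. These tests cannot pass a threshold of 0.05 in this design. No pair of libraries agreed within sampling noise, since the chi-square per gene lay between 11.97 and 43.96 over the 15 pairs.

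**Figure D2:**
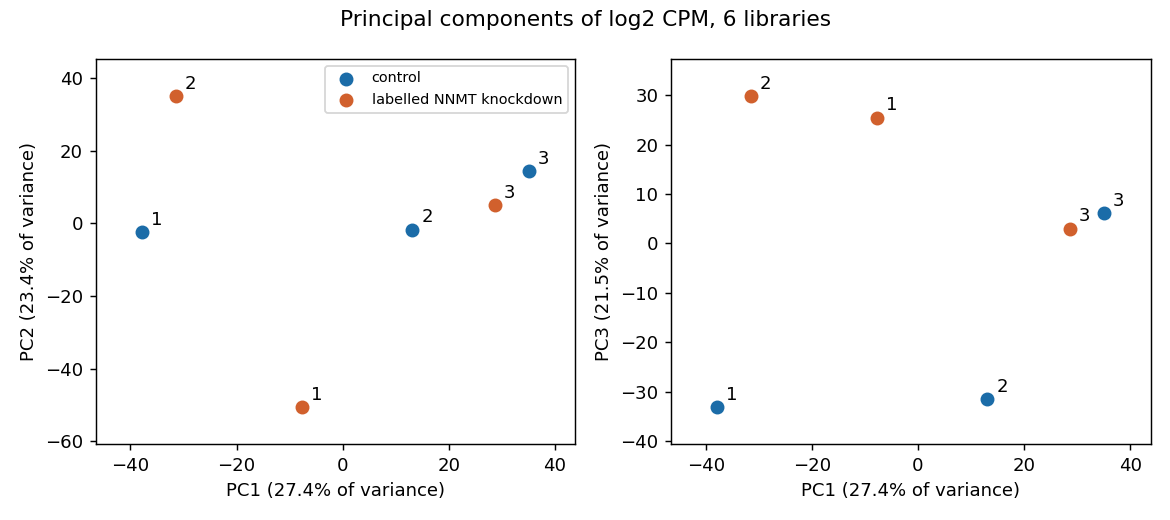
Principal components of log2 CPM over the tested genes, with 1 point per library, coloured by group and numbered by replicate; axes give component scores and their share of the variance. Control replicate 3 and replicate 3 labelled NNMT knockdown lie close together on the first component, at 35.1 and 28.7, and the groups overlap on it.

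The central comparison asked which genes changed between the libraries labelled NNMT knockdown and control. The transmembrane gene SIDT1, AKR1C1 and AKR1C2, which encode aldo-keto reductases of steroid metabolism, and TCN1, which encodes the vitamin B12 carrier haptocorrin, had lower levels in the libraries labelled knockdown. So did DSP, which encodes the desmosome protein desmoplakin. KAZN, which encodes the desmosome-associated protein kazrin, and the lysyl oxidase gene LOXL1 had higher levels. None of these differences passed the adjusted threshold in edgeR's quasi-likelihood test. Of 20250 genes tested, 0 rose and 0 fell at an adjusted p under 0.05, 0 of them by at least 2-fold, and the smallest adjusted p was 0.999. An unadjusted p under 0.05 was found for 817 genes, or 4.03%, against 1012 expected by chance, with 401 higher and 416 lower. The groups did not overlap for 1857 genes, or 9.17%, where chance gives 10%.

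The 5 genes with the lowest p among those lower in the libraries labelled NNMT knockdown were SIDT1, TCN1, AKR1C2, AKR1C1 and PCSK5, and each had an adjusted p of 0.9995 in edgeR's quasi-likelihood test. TCN1 (chromosome 11, 59852800 to 59866489) measured 103 ± 9.81 CPM in control and 52.4 ± 13.7 CPM in the labelled libraries (SD, n = 3), with a log2 fold change of -0.98 (SE 0.177). SIDT1, a SID1-family transmembrane gene (chromosome 3, 113532555 to 113629575), measured 8.57 ± 1.79 and 2.73 ± 1 CPM, with a log2 fold change of -1.65 (SE 0.283). AKR1C1 (chromosome 10, 4963253 to 4983283) measured 8.02 ± 2.58 and 3.36 ± 0.815 CPM. AKR1C2 (chromosome 10, 4987775 to 5018031) measured 1.51 ± 0.895 and 0.262 ± 0.112 CPM. The AKR1C genes are close paralogs, so their reads can be split or lost in counting and their values are uncertain. PCSK5, a proprotein convertase gene, measured 1.57 ± 0.347 and 0.432 ± 0.264 CPM.

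The 5 genes with the lowest p among those higher were KAZN, RPS27P3, LOXL1, RN7SL1 and ROMO1, again each with an adjusted p of 0.9995 in edgeR's quasi-likelihood test. KAZN (chromosome 1, 13892792 to 15118043) measured 2.99 ± 0.334 CPM in control and 6.17 ± 1.44 CPM in the libraries labelled NNMT knockdown (SD, n = 3), with a log2 fold change of 1.05 (SE 0.219). LOXL1 (chromosome 15, 73925989 to 73952137) measured 128 ± 5.39 and 170 ± 15.3 CPM, and ROMO1, a gene for a mitochondrial membrane protein, measured 29.9 ± 3.76 and 41.7 ± 3.83 CPM. RN7SL1, the RNA of the signal recognition particle, measured 16.5 ± 2.02 and 49.5 ± 19.9 CPM. RN7SL1 has many near-identical copies and RPS27P3 is a pseudogene of a ribosomal protein gene, so both values are uncertain.

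The calls differed between tools. DESeq2 called 8 genes at an adjusted p under 0.05, namely KAZN and RN7SL1 higher and SIDT1, TCN1, DSP, AKR1C1, AKR1C2 and AKR1E2 lower, the last of these named after its values were seen. The smallest adjusted p in DESeq2 was 2.97e-05, for SIDT1. The edgeR test without a filter on low counts called 72 genes, 7 of them shared with DESeq2, while limma-voom called 0. Of the named genes it called 19: SIDT1, TCN1, AKR1C1, AKR1C2, DSP, PRSS8, SPINT1, PCSK5, PDGFRA, MMP13 and AMOTL1 lower, and KAZN, LOXL1, ROMO1, AOX1, RPS29, ANGPTL4, CXCL1 and DLC1 higher. In the unfiltered fit the SE of LOXL1, RPS29 and AOX1 were nearly equal, at 0.0984, 0.0985 and 0.099. With the filter they were 0.0936, 0.11 and 0.172. Calls of the unfiltered fit may therefore take little account of the spread of single genes. Without control replicate 3 the edgeR test called 1 gene, ADCY1, also named after its values were seen. For the 11518 genes at a mean of at least 5 CPM, the 95% interval of the fold change lay within 2-fold in 97.4%, so changes above 2-fold lay outside it for most genes at that level. Over all tested genes the share was 70.8%.

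The enzyme encoded by NNMT uses nicotinamide and S-adenosylmethionine, and the lists for both pathways were fixed in advance. Of the 27 tested members of nicotinamide and NAD metabolism, 0 passed over all genes and 0 adjusted over the list alone, and the list did not pass camera (adjusted p = 0.944). Its median log2 fold change was -0.00442 while camera's direction was up. The aldehyde oxidase gene AOX1 had the lowest p of its members, with 157 ± 17.8 CPM in control and 207 ± 48.2 CPM in the libraries labelled NNMT knockdown (SD, n = 3). Without the filter on low counts AOX1 passed over all genes (log2 fold change 0.399, adjusted p = 0.0331 in edgeR's quasi-likelihood test). Its SE was 0.099 there, against 0.172 in the main fit. Its groups overlapped, with 157 CPM in replicate 3 labelled knockdown and 162 and 172 CPM in control replicates 1 and 3. Of 29 tested members of the methionine cycle and polyamine list, 0 passed over all genes or adjusted over the list alone (list adjusted p = 0.496). The spermine oxidase gene SMOX measured 35.7 ± 3.75 and 47.3 ± 5.23 CPM. The lists of 24 folate and serine genes and 7 sirtuins did not pass (each with an adjusted p of 0.832), and 0 of their members passed; the lowest p among them were those of PSAT1 and SIRT3.

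Enzymes that use methyl donors or remove methyl groups from chromatin were also compared. Of 38 histone methyltransferase genes, 0 passed over all genes or adjusted over the list alone, and the list had an adjusted p of 0.725 in camera. SUZ12, a Polycomb complex member, measured 95.7 ± 6.63 CPM in control and 74.7 ± 7.69 CPM in the libraries labelled NNMT knockdown (SD, n = 3). Of 23 histone demethylase genes and 15 DNA methylation genes, 0 passed over all genes or adjusted over the list alone, and the list adjusted p values were 0.74 and 0.944. KDM1A measured 173 ± 5.34 and 193 ± 10.7 CPM, and TDG measured 71.8 ± 4.59 and 63.4 ± 3.43 CPM.

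Over all 41 lists tested, 9 passed camera with a preset correlation of 0.01, of which 5 rose and 4 fell in the libraries labelled NNMT knockdown. None of the 9 held with an estimated correlation, where each had an adjusted p of 0.95, and fry called 0 lists, with a smallest adjusted p of 0.455. With an estimated correlation the smallest adjusted p of all 41 lists was also 0.95, so it does not rank the 9. Their unadjusted p in that camera test ran from 0.0568 for replication-dependent histones to 0.685 for G2 and M phase genes. Camera with an estimated correlation was not run on the simulated data, so whether it could call a shifted list here is not known. No list had a member that passed over all genes in the main test.

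Among the lists that rose were 2 housekeeping groups. Of 78 ribosomal protein genes, 68 lay above 0, with a median log2 fold change of 0.107 and an adjusted p of 3.02e-09 in camera (adjusted p = 0.95 with an estimated correlation). Of its members, 0 passed over all genes or adjusted over the list alone. RPS29 measured 133 ± 17.6 CPM in control and 179 ± 14.2 CPM in the labelled libraries, and RPL28 measured 437 ± 36.5 and 542 ± 11.6 CPM (SD, n = 3). Without the filter on low counts RPS29 passed over all genes (adjusted p = 0.0131 in edgeR's quasi-likelihood test). Of 77 nuclear-encoded subunits of oxidative phosphorylation, 62 lay above 0, with a median of 0.0714 and an adjusted p of 9.47e-05 (adjusted p = 0.95 with an estimated correlation), and NDUFA3 measured 30 ± 2.49 and 35.9 ± 1.12 CPM. The ribosomal protein list did not pass without control replicate 3 (median 0.0332, adjusted p = 0.541). The oxidative phosphorylation list did not pass without that library (median 0.0198, adjusted p = 0.538) or without replicate 2 labelled knockdown (median 0.0296, adjusted p = 0.358).

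The other lists that rose concerned cholesterol synthesis and the cell cycle. Of 26 cholesterol synthesis genes, 20 lay above 0, with a median of 0.101 (adjusted p = 0.00409, and 0.95 with an estimated correlation); PMVK measured 25.6 ± 0.821 and 30.2 ± 2.18 CPM in control and labelled libraries (SD, n = 3). Of 69 genes of G2 and M phase, 54 lay above 0 (median 0.0889, adjusted p = 0.0435, and 0.95 with an estimated correlation). Of 63 genes of S phase, 48 lay above 0 (median 0.0806, adjusted p = 0.0499, and 0.95 with an estimated correlation). KIF20B and UBR7 had the lowest p in these lists, and 0 members of any of these lists passed over all genes or adjusted over the list alone. The G2 and M phase list turned to a median of -0.0695 without replicate 2 labelled knockdown and to -0.00331 without control replicate 3. Without the same libraries the S phase list had medians of -0.0261 and 0.0271, and camera's direction was down in both. With an offset for gene length, chosen after the data were seen, neither list passed (adjusted p = 0.0608 for G2 and M phase and 0.0686 for S phase), nor did the S phase list with libraries thinned to the smallest (adjusted p = 0.0512). The cholesterol synthesis list passed in 2 of the 6 fits that left out a library.

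Of the lists that fell, that of replication-dependent histones had the lowest median, -0.231, with 27 of 31 members below 0 (adjusted p = 0.000172 in camera, and 0.95 with an estimated correlation). H4C8 measured 40.8 ± 3.26 CPM in control and 31.2 ± 3.02 CPM in the labelled libraries (SD, n = 3). The transcripts of these genes mostly lack poly(A) tails, while the libraries were made from poly(A) RNA. The median level of the listed members was 0.588 CPM, so the list may not represent the bulk of these transcripts. Of 34 epithelial genes, 26 lay below 0, with a median of -0.149 (adjusted p = 0.00115, and 0.95 with an estimated correlation). Of these, 3 fell when adjusted over the list alone, each with an adjusted p of 0.0358 in edgeR's quasi-likelihood test, and 0 passed over all genes, although all 3 did without the filter on low counts. PRSS8, the gene of the membrane protease prostasin, measured 4.69 ± 1.72 and 1.87 ± 0.688 CPM, the protease inhibitor gene SPINT1 measured 58.5 ± 7.38 and 42.3 ± 5.81 CPM, and DSP measured 68.9 ± 17.5 and 33 ± 8.48 CPM. CDH1, which encodes E-cadherin, measured 39.9 ± 9.48 and 31.7 ± 3.19 CPM and did not pass. The histone list did not pass without control replicate 1 (adjusted p = 0.0575), nor the epithelial list without replicate 1 labelled knockdown (adjusted p = 0.0525) or control replicate 3 (adjusted p = 0.254).

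Immediate early genes, which respond within minutes to growth factors, had 29 of 37 members below 0 (median -0.143, adjusted p = 0.00115, and 0.95 with an estimated correlation). ATF3 measured 10.7 ± 0.865 CPM in control and 7.41 ± 1.24 CPM in the labelled libraries (SD, n = 3), and PHLDA1 measured 204 ± 24 and 163 ± 13 CPM. Genes of the unfolded protein response had 24 of 36 members below 0 (median -0.0772, adjusted p = 0.0196, and 0.95 with an estimated correlation), and DNAJB11, a chaperone gene of the endoplasmic reticulum, measured 87.4 ± 1.57 and 70.4 ± 5.61 CPM. In both lists 0 members passed over all genes or adjusted over the list alone. They passed in 3 and 2 of the 6 fits that left out a library, and the unfolded protein response list did not pass with the offset for gene length (adjusted p = 0.0608).

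**Figure D3:**
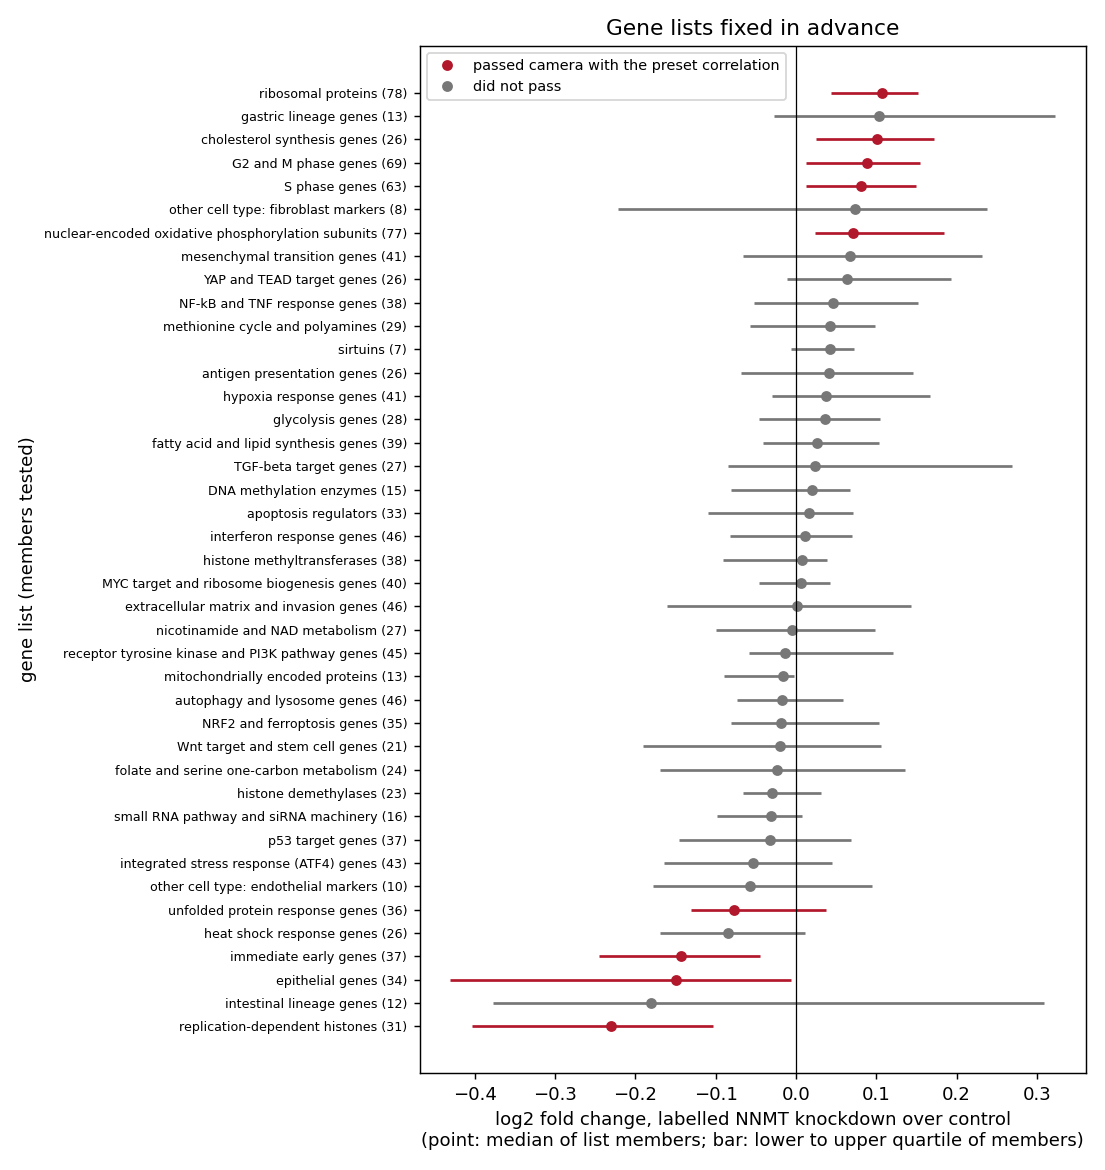
Median log2 fold change of each gene list, libraries labelled NNMT knockdown over control, with bars from the lower to the upper quartile of members and the number of tested members in parentheses. Red lists passed camera with the preset correlation; 5 lie above 0 and 4 below, and none passed with an estimated correlation (adjusted p = 0.95).

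Lists that bear on invasion did not pass in the main test. Of 41 mesenchymal transition genes, 27 lay above 0 (adjusted p = 0.279 in camera). Without replicate 1 labelled NNMT knockdown that list passed, with a median of 0.0936 and an adjusted p of 0.0401 (adjusted p = 0.889 with an estimated correlation). Of 46 extracellular matrix and invasion genes, 24 lay above 0 (adjusted p = 0.832). LOXL2 measured 219 ± 16.6 CPM in control and 261 ± 20.9 CPM in the libraries labelled NNMT knockdown, and LAMA4 measured 7.86 ± 2.69 and 4.81 ± 1.06 CPM (SD, n = 3). In the list of 35 NRF2 and ferroptosis genes, AKR1C1 and AKR1C2 fell when adjusted over the list alone, each with an adjusted p of 0.0183 in edgeR's quasi-likelihood test, and 0 members passed over all genes in the main test (list adjusted p = 0.673). Both are close paralogs, as stated above.

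Lists of responses to foreign RNA and of markers of other cells did not pass either in the main test. Of 46 interferon response genes, 24 lay above 0 (adjusted p = 0.279 in camera). That list passed without control replicate 3 (median 0.683, adjusted p = 1.37e-43) and with the replicate number as a block (median 0.253, adjusted p = 0.000695). With an estimated correlation it passed in neither, with adjusted p = 0.509 and adjusted p = 0.902. The list of small RNA pathway genes had an adjusted p of 0.431, with 78.3 ± 8.93 and 68 ± 9.86 CPM for AGO4 in control and labelled libraries (SD, n = 3). Fibroblast and endothelial marker lists each had an adjusted p of 0.832. Of 16 leukocyte markers only 3 were tested, too few for camera. CD14 fell when adjusted over the list alone (adjusted p = 0.0177 in edgeR's quasi-likelihood test), at 0.822 ± 0.263 CPM in control and 0.289 ± 0.0791 CPM in the labelled libraries.

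**Figure D4:**
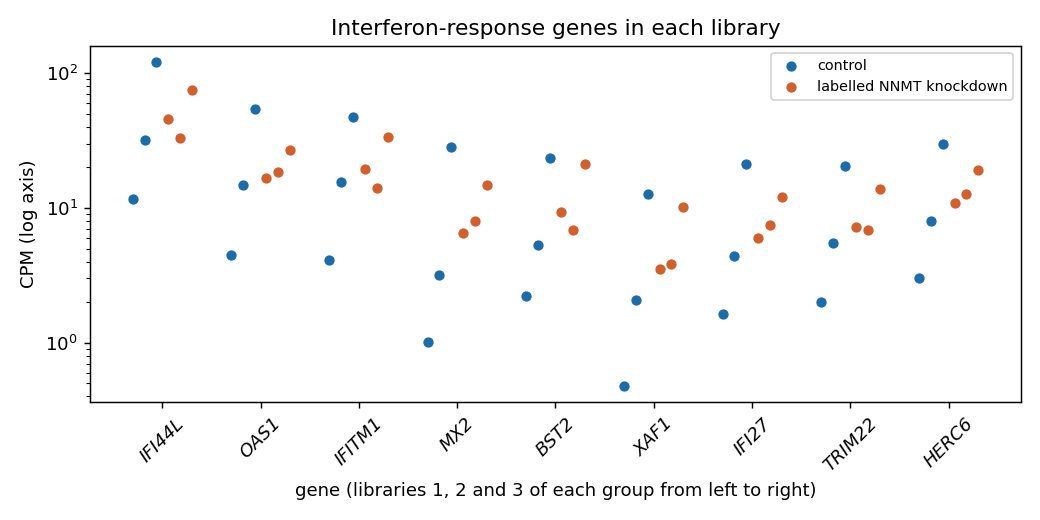
Levels of 9 interferon response genes, chosen after their values were seen, in each library in CPM on a log axis, with blue points for control and orange points for libraries labelled NNMT knockdown. Levels spread within the control group more than between groups; IFI44L lay between 11.7 and 121 CPM in control libraries and between 33.2 and 74.7 CPM in the labelled libraries.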

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

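Halved counts, the offset for gene length, the restriction to protein-coding genes, and an estimated correlation with a library left out or a block were tests chosen after the data were seen. The edgeR test called 0 genes under each scaling, the stricter filters and thresholds, glmTreat, non-robust dispersion, thinned or halved counts, the length offset and protein-coding genes alone, as did limma-voom. Without a filter on low counts it called 72 genes, 16 of them changed at least 2-fold, and DESeq2 called 8 and 7, with 7 genes called by both and 2 adjusted p values given as NA. The fold of TCN1 was alike without the filter (log2 -0.982) while its SE was 0.102, against 0.1767 with it; the cause was not tested. Leaving out a library gave 0 to 1 genes, and 0 to 1 changed at least 2-fold; the gene called without control replicate 3 was ADCY1. Of the named genes, 20 passed under an alternative without passing in the main test, 19 without the filter and 7 in DESeq2, 6 of them under both.

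The log2 fold change of NNMT lay between 0.369 and 0.905 under 13 settings with all libraries, and between -0.188 and 1.06 when a library was left out; it was below 0 without replicate 3 labelled NNMT knockdown and, at -0.0428, without control replicate 1. The smallest p among all of these was 0.382. Its 44 reads in all limit what depth can show.

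Of the gene lists, 9 passed under each scaling, each filter, limma-voom, non-robust dispersion, halved counts and protein-coding genes alone, and the same 9 each time. Thinning gave 8, losing S phase, and the length offset 6, losing G2 and M phase, S phase and the unfolded protein response. Leaving out a library gave 4 to 12, with 4 without control replicate 2 and 5 without control replicate 3. Lists gained were mesenchymal transition (up) without replicate 1 labelled NNMT knockdown; glycolysis and hypoxia (up), heat shock and MYC targets (down) without replicate 2; and YAP and TEAD targets (up), ATF4 and mitochondrially encoded genes (down) without replicate 3. ATF4 genes (down) were gained without control replicate 1, and antigen presentation, interferon (up) and heat shock (down) without control replicate 3. Camera with an estimated correlation gave 0, as it did without each library and with the replicate block, and fry gave 0, and 2 of the tested lists had a member past the threshold adjusted over the list alone. DESeq2 gave no camera result. The cause of these shifts was not tested.

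With a library left out, the median of the G2 and M phase list ranged from -0.0695 to 0.263, and was -0.00331 without control replicate 3. That of the S phase list ranged from -0.0261 to 0.196, and was 0.0271 without control replicate 3, where camera's direction was down. The log2 fold changes of 8 genes that passed in no setting also changed sign. MUC5AC ranged from -0.567 to 1.94, IRF9 from -0.0407 to 0.484, HERC5 from -0.642 to 0.299, STAT2 from -0.289 to 0.035, and IFIT2 from -0.0174 to 0.681, with -0.0131 without control replicate 1. CSF1R ranged from -0.367 to 0.102, with 0.0443 and 0.0715 without control replicates 2 and 3. SIRT2 ranged from -0.00234 to 0.0944 and SIRT6 from -0.092 to 0.17. The cause was not tested.

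With the replicate number as a block, 0 genes passed (smallest adjusted p 0.263), 0 of them at least 2-fold, and 11 lists passed, gaining gastric lineage and interferon response genes (both up; each adjusted p = 0.902 with an estimated correlation, where 0 lists passed). Deviations from the group means correlated at 0.055, -0.0869 and 0.2 between libraries of the same number, and replicate 2 labelled NNMT knockdown correlated best with control replicate 1, at 0.151. The numbers were therefore not taken to pair the samples.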

Other observations

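The tests of NNMT read number, of sequencing depth, of fibroblasts and of the offset for gene length were chosen only after the result was seen. Interferon response genes had the widest range over the 6 libraries of the 41 lists tested. The mean log2 level of 46 members relative to the average library was -0.962, -0.392 and 0.968 in control replicates 1, 2 and 3, and -0.03, -0.0871 and 0.504 in replicates 1, 2 and 3 labelled NNMT knockdown, a range of 1.93. An exact permutation test of the group difference gave p = 0.8, but it cannot go below 0.1 here. The list passed camera without control replicate 3 (median log2 fold change 0.683, adjusted p = 1.37e-43), but not there with an estimated correlation of 0.607 (adjusted p = 0.509). IFI44L measured 11.7, 31.8 and 121 CPM in the control libraries, OAS1 measured 4.5, 14.8 and 54 CPM, and MX2 measured 1.01, 3.21 and 28.2 CPM. Antigen presentation genes had their extremes in the same libraries, at -0.479 in control replicate 1 and 0.412 in control replicate 3. The genes in this paragraph and the next were named after their values were seen.

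Some single genes had a wide range within groups. CEACAM5, a carcinoembryonic antigen gene, measured 0.289, 4.27 and 26.8 CPM in control replicates 1, 2 and 3 and 0.74, 12.9 and 3.11 CPM in the libraries labelled NNMT knockdown. TFF3, a trefoil factor gene, measured 0.481, 4.73 and 15.8 CPM in control and 2.71, 3.9 and 15.9 CPM in the labelled libraries. MUC5AC stood at 42.5 CPM in replicate 2 labelled knockdown and between 3.67 and 8.97 CPM in the other 5 libraries. Receptor gene MET lay between 398 and 455 CPM in all 6 libraries. Epithelial genes as a list had a range of 0.889 over the libraries, from -0.373 in control replicate 1 to 0.516 in control replicate 3.

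Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real split gave 0 genes and 0 genes changed at least 2-fold; every split reaches 0, so the counts of 10 of 10 say nothing about chance. The highest other splits gave 29 and 15. It gave 9 lists, which 7 of 10 splits reached, against 15 in the highest other. The 29 genes were found when replicates 1 and 2 labelled NNMT knockdown and control replicate 1 were set against the rest, where 13.6% of genes had an unadjusted p under 0.05, and again when replicates 1 and 3 labelled knockdown and control replicate 3 were set against the rest. In the first of these splits the named libraries held 2, 8 and 0 NNMT reads, against 14, 8 and 12 in the rest. In the second they held 2, 14 and 12, against 8, 0 and 8. Differences in so few reads were not tested between these splits. Of the other 9 splits, 6 gave 0 genes and 1 gave 2. In the first split the named libraries scored -7.65, -31.5 and -37.8 on the first principal component. The rest, replicate 3 labelled knockdown and control replicates 2 and 3, scored 28.7, 13.1 and 35.1. Both results come from the same values, so the scores are no separate support for that split. The 29 genes may reflect a structure of the samples other than the labelled groups. Whether 29 exceeds the highest of 9 chance splits was not tested.

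NNMT was near 0 in all 6 libraries and was not lower in those labelled knockdown. With so few reads, the lower 95% bound of the ratio to control was 0.336, above the ratio of 0.3 set for a knockdown, but it lay at or below 0.3 under 6 of 19 alternatives, from 0.148 to 0.436 over all of them, so a knockdown can be neither shown nor excluded. Exchanged libraries would make another split call many genes only if the knockdown changed many genes, which was not shown. The highest other split called 29, between the bounds of 20 and 100 set for this test. This count cannot decide the question, so an exchange of libraries between the groups stays open. The biological explanation, that the transfected RNA did not change NNMT in these cells, was not tested.

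Ribosomal protein and oxidative phosphorylation lists lay above 0 in the libraries labelled NNMT knockdown while 0 single genes passed. The mean log2 level of ribosomal protein genes relative to the average library was 0.0438, 0.0217 and -0.232 in control replicates 1, 2 and 3. It was 0.12, 0.0461 and -0.000183 in replicates 1, 2 and 3 labelled knockdown. An exact permutation test gave p = 0.4, where 0.1 is the smallest possible. Without control replicate 3, the lowest, the list did not pass camera (median 0.0332, adjusted p = 0.541). The oxidative phosphorylation list was also lowest there, at -0.164. Against genes matched on length and expression, the ribosomal protein median of 0.107 was in excess by 0.0857 (permutation p = 1e-04 over genes, the smallest that 10000 random draws can give) and the oxidative phosphorylation median of 0.0714 by 0.045 (permutation p = 0.015), though the draws ignore the correlation of list members. Both lists also passed camera at the preset correlation with an offset for gene length (medians 0.0959 and 0.0609, adjusted p = 5.37e-06 and 0.00146). The matched genes were longer than the lists. Their median was 3972 bases against 3208 for the ribosomal protein list, and 2998 against 2615 for the oxidative phosphorylation list. Gene length was that of merged exons and not of the transcripts present. These tests therefore cannot decide on a bias towards short transcripts. Correlated expression is a candidate explanation of both calls. With an estimated correlation of 0.683 the ribosomal protein list had an adjusted p of 0.95 in camera. At the preset correlation, 8 of the 9 other splits also called it. For the oxidative phosphorylation list the estimated correlation was 0.468 and the adjusted p in camera was 0.95. As no list tested had a lower adjusted p with an estimated correlation, these adjusted p values alone cannot decide on correlated expression. A response to the transfected RNA stays open as untested.

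Most gastric and intestinal lineage genes were near 0, with 4 above 50 CPM in every library, while the mesenchymal transition list had a median of 49.3 CPM, with 6 of 46 members below 1 CPM in all libraries. Low depth is argued against, as 44 of 65 members had an upper counting bound below 1 CPM over 275 M reads, and 15 had 0 reads. A loss of reads that overlap several genes was not tested. Fibroblasts as the source of the mesenchymal genes are argued against by DCN, LUM, THY1 and POSTN, whose highest level was 2.35 CPM while COL6A1 averaged 4620 CPM; other fibroblast markers were present, with COL1A1 at 275 ± 41.4 and 370 ± 130 CPM and PDGFRA at 34.6 ± 4.24 and 21.4 ± 7.31 CPM in control and labelled libraries (SD, n = 3), so a small share is not excluded. HOXB13, a prostate and hindgut gene picked after its value was seen, lay between 442 and 568 CPM. A mislabelled or different cell line was not decided by these tests and stays open, and no biological explanation was tested.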
